A study of Homo sapiens with 6 samples.

How the data were processed

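The series comprises ChIP-seq of MV4;11 cells with antibodies against H3K79me2 (ab3594) and RNA polymerase II (CTD4H8), per the labels. Formaldehyde cross-linked chromatin was sonicated before immunoprecipitation, and libraries were made with a ThruPLEX-FD kit, per the labels' protocols. Treatments were 0.1% DMSO, 5 µM SGC0946 for 8 h, and SGC0946 for 8 h with washout. The labels give no washout time and name no replicates, so each of the 6 groups is 1 library. The titles of the DMSO libraries carry a number 2 after ChIP whose meaning is not given, and the labels state no batch or date. Groups were taken from the sample titles, and the treatment characteristics were read beside them. Titles, sources and treatments of the washout libraries all name the washout, while the names of their deposited lists carry DOT1L and the word "with". The labels were followed, and every washout value rests on them. The treatment protocol also names the BET inhibitor I-BET151, which no sample label used here carries. Control (input) libraries were not analysed here.

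Reads were aligned with BWA 0.6.2-r126 and peaks were called with MACS2 on hg19, per the submitters' processing notes. The MACS2 version, the calling options and the control used are not given in the sources used here. The authors deposited 1 peak list per library, with the chromosome, start and end of each peak, a peak name carrying 1 library name, and a score. Each deposited score was read as the −log10 of the MACS2 q value, since the lowest score in each list (1.31 to 1.34) lies just above 1.30, the −log10 of 0.05. This reading is inferred from the values. Scores are the authors' own values for each library. They were used to rank or filter peaks within a list. Where the same score limit of 10 was applied to lists of different treatments, the counts also depend on the depth of each library, which is unknown. The lists give neither read counts nor coverage, so depth is unknown, the signal at an absent peak is unknown, and no fold change could be computed. A peak absent from a list is one that the caller did not report. No spike-in or other external scale is given in the sources used here.

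Starts were converted to 1-based positions for printing, and peaks on chromosomes and unplaced scaffolds were all kept. A peak was counted as shared when it had at least 1 bp in common with a peak of the other list, and otherwise as absent. Overlaps were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 and checked against bedtools 2.31.1, exact binomial intervals were computed with scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. As a background, the other list was rotated along each chromosome by a random distance, 100 times with seed 7. No p-value was computed between treatments. Covered length, the share of bases shared, coverage of wide peaks and the number of pieces in the other list were computed from the peaks as deposited. Peaks were joined only where this is stated. For score-matched comparisons, DMSO peaks were split into 10 groups by score. Shares of peaks were weighted by the number in each group of the peaks under study, those absent after SGC0946 or those on absent H3K79me2 peaks. For bases under and outside Pol II, the plain mean of the 10 group differences was taken. Wide DMSO H3K79me2 peaks of 5 kb or more were divided into 5 equal parts. The overlap of each with its strongest DMSO Pol II peak was located. Where the middle of this overlap lay in an outer part, the H3K79me2 peak was turned so that this part came first.

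The overlap step was tested on simulated data in which peaks drawn at random were removed from a copy of the list. All 21318 peaks removed from the 84972 of the H3K79me2 DMSO list and all 24610 removed from the 98523 of the Pol II DMSO list were found absent, and 0 kept peaks were. The score-matched difference between sets of peaks was tested on the 84972 H3K79me2 peaks with planted differences of 0 and -15 percentage points, which came out as 0.023 and -15.035. The score-matched difference in bases under and outside Pol II is another calculation and was not tested in this way.

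The groups, the comparisons, the processing settings to be varied and the rule for named regions were fixed before the data were examined. The rule names, for each antibody, the 5 longest DMSO peaks absent from the treated list and the 5 longest treated peaks absent from DMSO. It replaced a rule on genes, because the gene table at hand is of another assembly (GRCh38) than the peak lists. For the same reason 12 planned counts of genes, the planned gene lists and the markers of other cell types were not computed, no gene was assigned to a peak, and positions are given as the files give them. The wide domains, the score groups, the position within domains and the bases under Pol II were not part of that design. They were added once the lists had been read.

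The settings varied were a stricter score of at least 10 in both lists compared, equal numbers of top-scoring peaks per antibody, a minimum overlap of 50% of the peak, joining peaks within 1 kb, and restriction to chromosomes 1 to 22 and X. With 1 library per group there was no replicate to leave out. Further alternatives chosen after seeing the data concern covered length, wide peaks, the strongest peaks, the comparison of bases under and outside Pol II, and position within domains.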

Results

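H3K79me2, the histone mark written by the methyltransferase DOT1L over transcribed genes, and RNA polymerase II (Pol II) were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in MV4;11 cells, a leukaemia line that carries an MLL fusion gene. Cells had received 0.1% DMSO as vehicle, 5 µM of the DOT1L inhibitor SGC0946 for 8 h, or the same exposure followed by washout of the compound, for a time the labels do not give. The washout libraries are those labelled so; the names of their lists instead carry DOT1L and the word "with", so whether the inhibitor had been removed rests on the labels. The 6 libraries covered each antibody and treatment with 1 library. There were therefore no replicates, no difference between treatments could be set against replicate error, and every comparison describes these libraries. The deposited peak lists hold no read counts, so the depth of each library is unknown and differences in depth were not separated from differences in chromatin. Percentages of peaks are given with exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only.

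The H3K79me2 list held 84972 peaks in DMSO, 93199 after SGC0946 and 67789 after washout. These peaks covered 90.2 Mb, 83.3 Mb and 56.0 Mb of the genome. The median peak was 468 bp wide in DMSO, 446 bp after SGC0946 and 438 bp after washout, and the widest was 66282 bp, 64502 bp and 31505 bp. The Pol II list held 98523 peaks in DMSO, 112095 after SGC0946 and 52178 after washout, covering 52.3 Mb, 59.3 Mb and 30.7 Mb. Its median widths were 316 bp, 308 bp and 362 bp.

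**Figure D1:**
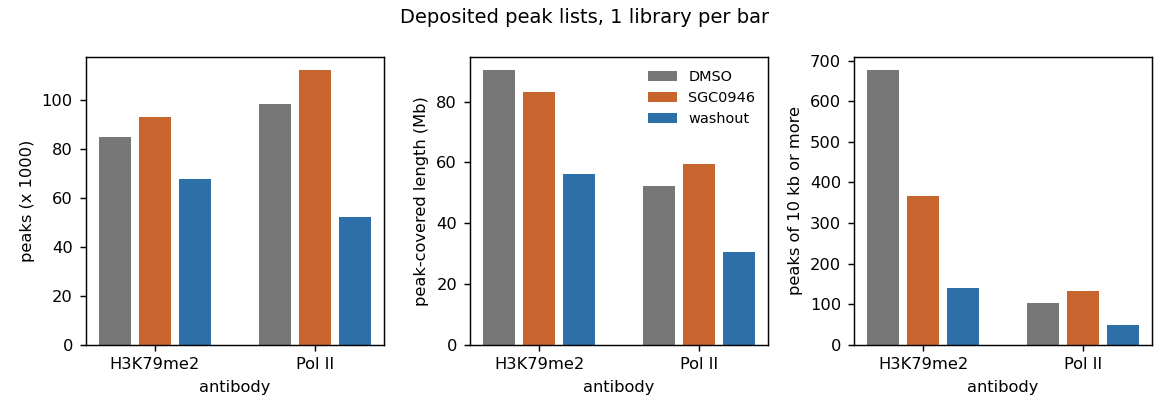
Number of peaks (in units of 1000), peak-covered length in Mb and number of peaks of 10 kb or more for H3K79me2 and Pol II, with 1 bar per library, coloured by treatment. The washout library had the shortest covered length of the 3 treatments for both antibodies, 56.0 Mb for H3K79me2 and 30.7 Mb for Pol II, and peaks of 10 kb or more numbered 676, 366 and 140 for H3K79me2 in DMSO, SGC0946 and washout.

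The first comparison asked how the H3K79me2 landscape stood after 8 h with the DOT1L inhibitor. Most of the landscape was still called: 64421 of 84972 DMSO peaks, or 75.8% (75.5 to 76.1%), shared at least 1 bp with a peak of the SGC0946 list, and 80.3% of DMSO H3K79me2 bases were covered there. The 20551 DMSO peaks absent after SGC0946 were narrow, with a median width of 265 bp against 634 bp for the shared peaks, and 792 of them had a score of 10 or more. In the other direction, 17086 SGC0946 peaks, 18.3% of that list, were absent from DMSO, with a median width of 251 bp. Circular shifts of the lists along the chromosomes gave a mean of 4.55% of DMSO peaks shared. When both lists were limited to peaks with a score of 10 or more, so that a partner with a lower score no longer counted, 5396 of 30063 DMSO peaks and 4391 SGC0946 peaks had no partner. After joining peaks within 1 kb, additional regions (6885) outnumbered absent ones (6311).

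The number of wide peaks differed more between these lists than their covered length did. H3K79me2 peaks of 10 kb or more numbered 676 in DMSO and 366 after SGC0946, and peaks of 5 kb or more held 27.0% of the covered bases in DMSO and 17.9% after SGC0946. The positions of the 676 wide DMSO peaks were nevertheless covered to a mean of 96.6% by SGC0946 peaks, in a median of 3 pieces, and 639 of them were covered to 90% or more. When peaks within 1 kb of each other were joined, 2793 regions of 10 kb or more were present in DMSO and 2615 after SGC0946, a change of -6.37%.

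The widest DMSO domain, on chromosome 16 from 89489432 to 89555713 (hg19, the build of the files), was covered to 99.1% after SGC0946 in 7 pieces. The domain beside it, from 89426379 to 89489244, was covered to 100% by a single piece. A 59035 bp domain on chromosome 19, from 15379827 to 15438861, was covered to 99.5% in 3 pieces. These domains were chosen for their width in DMSO after the data were examined.

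Among the 5 longest DMSO H3K79me2 peaks absent after SGC0946, none exceeded 1631 bp. The longest was on chromosome 7 from 17956272 to 17957902, had no Pol II peak in any library, and was covered to 41.9% by washout peaks. The fourth, on chromosome 1 from 245011692 to 245013147, had the highest score of these 5 regions, 24.0, and was absent after washout as well. Pol II peaks covered it to 95.1% in DMSO, 97.2% after SGC0946 and 93.1% after washout. The longest H3K79me2 peak present after SGC0946 and absent in DMSO was on chromosome 12 from 76911961 to 76913787, with a score of 6.59.

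The washout library was compared with DMSO and with SGC0946 to show where H3K79me2 stood after the inhibitor had been removed. It stood further from DMSO than the SGC0946 library did: 42981 DMSO peaks, 50.6% (50.2 to 50.9%), shared a base with a washout peak, and 56.4% of DMSO H3K79me2 bases were covered. The other 41991 DMSO peaks were absent, 4758 of them among the 30063 with a score of 10 or more. The washout list was largely a subset of the earlier ones, since 88.4% of its peaks (88.1 to 88.6%) were in the DMSO list and 86.5% (86.2 to 86.8%) in the SGC0946 list. Against SGC0946, 42982 of 93199 peaks were absent after washout and 9151 washout peaks were absent from SGC0946. With both lists limited to scores of 10 or more, 15493 of 30063 DMSO peaks had no washout partner that also reached this score, and 742 washout peaks had no such DMSO partner.

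The fate of DMSO peaks was followed through both treatments. Of the 20551 DMSO H3K79me2 peaks absent after SGC0946, 3618, or 17.6% (17.1 to 18.1%), were present after washout. Of the DMSO peaks present after SGC0946, 61.1% were present after washout, and 36.7% when these were weighted to the DMSO scores of the absent peaks. Both absences were judged against the same DMSO list, so marginal DMSO calls can be absent from both lists more often whatever the treatment. No value for unchanged libraries could be set beside these shares. Peaks found in SGC0946 and not in DMSO were present after washout in 15.7% of cases. In all 3 lists together, 39363 DMSO peaks, 46.3%, were present, and 16933, 19.9%, were in the DMSO list alone.

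The share of DMSO peaks found again depended on the score the caller had given them in DMSO, a score read as the negative log10 of the q value. When DMSO H3K79me2 peaks were ranked by score and split into 10 groups of nearly equal size, 45.0% of group 1, the lowest scores, were present after SGC0946 and 18.9% after washout. In group 10 the shares were 99.9% and 98.3%. Pol II peaks gave 45.3% and 14.3% in group 1, and 99.9% and 97.4% in group 10.

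**Figure D2:**
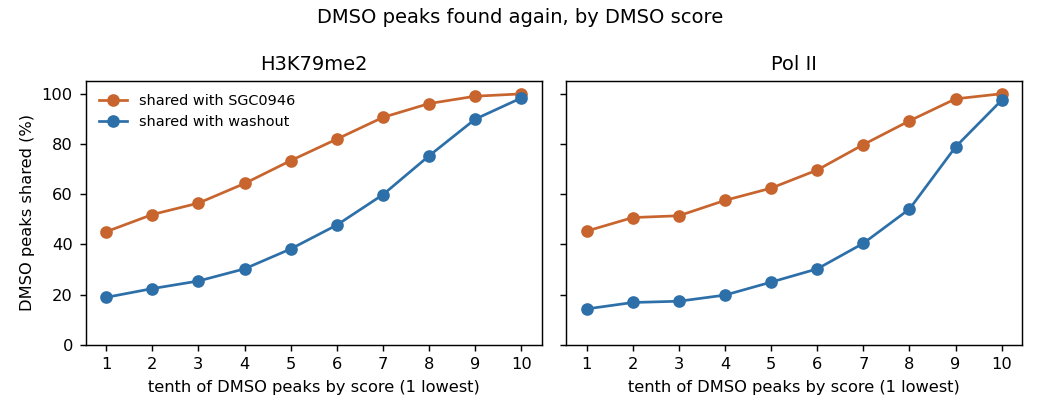
Percentage of DMSO peaks sharing at least 1 bp with a peak of the SGC0946 or washout list (vertical axis), by group of DMSO score from 1, the lowest, to 10, the highest (horizontal axis), for H3K79me2 and Pol II. The washout line lies below the SGC0946 line in all 10 groups for both antibodies, by the widest margin in the middle groups, and the lines meet within 3 percentage points in group 10.

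Wide H3K79me2 domains were covered less completely after washout than after SGC0946. The 676 DMSO peaks of 10 kb or more were covered to a mean of 81.9% in a median of 5 pieces, 231 of them to 90% or more and 21 of them to under 50%, and each kept at least 1 peak. The widest domain on chromosome 16 was covered to 96.7% in 14 pieces, and the chromosome 19 domain to 89.1% in 9 pieces. Regions of 10 kb or more after joining peaks within 1 kb numbered 1489, a change of -46.7% from DMSO. Covered length after washout, as a percentage of DMSO, ran from 57.1% on chromosome 21 to 68.8% on chromosome 8 among the 22 autosomes, and was 47.7% on chromosome X.

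Within domains, coverage after washout was highest near the Pol II end. Of 2725 DMSO H3K79me2 peaks of 5 kb or more, 1612 had the overlap with their strongest DMSO Pol II peak centred in the first or last of 5 equal parts. These were turned so that this end came first. Washout H3K79me2 peaks covered a mean of 86.0% ± 0.59 (SE over 1612 regions of 1 library) of the part at the Pol II end, 90.3% ± 0.51 of the next, 82.8% ± 0.64 of the middle, 69.3% ± 0.85 of the one after and 52.4% ± 0.95 at the far end. SGC0946 peaks covered 97.1%, 97.5%, 96.6%, 96.2% and 90.7%. The difference between the Pol II end and the far end was 33.6 ± 1.20 percentage points after washout and 6.42 ± 0.33 points after SGC0946.

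**Figure D3:**
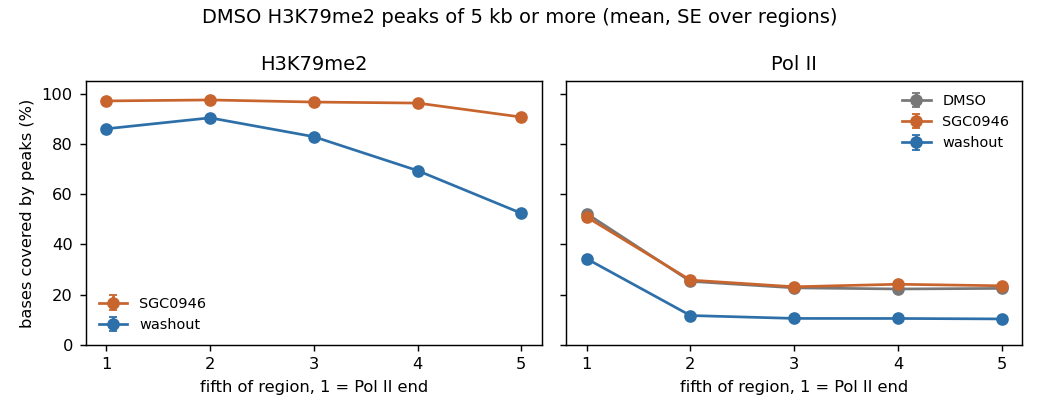
Mean percentage of bases covered by peaks (vertical axis; error bars, SE over 1612 regions, smaller than the points) in 5 equal parts of DMSO H3K79me2 peaks of 5 kb or more, from the end with the strongest Pol II peak, part 1, to the far end, part 5 (horizontal axis). H3K79me2 coverage after washout goes from 86.0% in part 1 to 52.4% in part 5, and Pol II coverage in part 1 is 52.2% in DMSO, 50.9% after SGC0946 and 34.2% after washout.

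The 5 longest DMSO H3K79me2 peaks absent after washout were 5780 to 8535 bp wide, and each of them overlapped Pol II peaks in all 3 treatments. The longest was on chromosome 10 from 120798650 to 120807184; SGC0946 H3K79me2 peaks covered 94.0% of it, and Pol II peaks covered 87.2% in DMSO, 80.9% after SGC0946 and 75.7% after washout. The region on chromosome 21 from 36212628 to 36219450 was covered to 97.3% by SGC0946 H3K79me2 peaks and to 100% by Pol II peaks in all 3 treatments. On chromosome 6, from 7233748 to 7240342, Pol II covered 98.9% in DMSO and 63.0% after washout. The region on chromosome 10 from 124921159 to 124926938 had Pol II coverage of 58.5% in DMSO and 49.7% after washout.

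Except for the region on chromosome 8, these were parts of broader domains that were partly called after washout. Once DMSO peaks within 1 kb were joined, the surrounding domains were 38333 to 45460 bp wide, and washout peaks covered 41.3% of the first, 11.2% of the one on chromosome 21, 28.6% of the one on chromosome 6 and 61.9% of the second on chromosome 10. The chromosome 8 region, from 128746914 to 128752867, was 5954 bp wide with a score of 82.8, above 97.0% of the DMSO list. SGC0946 H3K79me2 peaks covered 81.0% of it and washout peaks none, the nearest washout peak being 53905 bp away. Pol II peaks covered 100% of it in all 3 treatments.

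**Figure D4:**
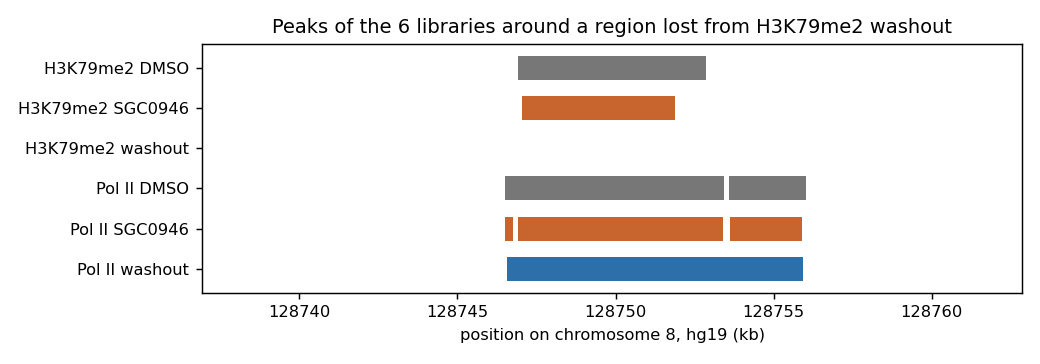
Peaks of the 6 libraries (bars, 1 line per library) on chromosome 8 around 128746914 to 128752867, with the position in kb on hg19 on the horizontal axis. H3K79me2 peaks are drawn in DMSO and SGC0946 and none in washout, and the Pol II washout peak runs from 128746570 to 128755917.

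H3K79me2 peaks present after washout and absent in DMSO were short. The longest, on chromosome 7 from 2873846 to 2875294, was 1449 bp wide with a score of 8.04, and SGC0946 peaks covered 52.4% of it. All 5 longest such peaks were partly covered in the SGC0946 list, from 9.76% on chromosome 5 (142242692 to 142243982) to that 52.4%.

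Pol II was compared across the same treatments. After SGC0946 its list was longer than in DMSO, 112095 against 98523 peaks. Of the DMSO Pol II peaks, 69303, or 70.3% (70.1 to 70.6%), were shared and 29220 were absent. Of the SGC0946 peaks, 44942, or 40.1%, were absent from DMSO, and 355 of these had a score of 10 or more. The longest of them lay on chromosome 15 from 59392320 to 59393921 and on chromosome 8 from 129100485 to 129101944, 1602 bp and 1460 bp wide, with no H3K79me2 peak in any treatment and scores of 6.30 and 10.7. The 103 DMSO Pol II peaks of 10 kb or more were covered to a mean of 98.8%, and all 103 to 90% or more.

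After washout 38821 DMSO Pol II peaks, 39.4% (39.1 to 39.7%), were present and 59702 were absent. Against SGC0946, 72921 peaks were absent and 7999 washout peaks were absent from SGC0946. These counts depend on the unequal lengths of the lists. With the 52178 top-scoring peaks of each list, 41.7% of DMSO peaks were absent after washout and 29.9% after SGC0946. Washout then lacked 21747 DMSO peaks and had 16283 absent from DMSO, and against SGC0946 the numbers were 22017 and 14966. Of the 18331 DMSO Pol II peaks with a score of 10 or more, 1886 were absent after washout and 165 after SGC0946. Strong sites were retained: of the top 5% of DMSO Pol II peaks by score, 4937 in number, 9 were absent after washout. The Pol II peaks of 10 kb or more were covered to a mean of 91.7%. Of the DMSO Pol II peaks absent after SGC0946, 9.50% (9.17 to 9.84%) were present after washout, and of those kept by SGC0946, 52.0% were, or 31.0% after weighting to the scores of the absent peaks.

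The longest DMSO Pol II peak absent after washout was on chromosome 19 from 18568179 to 18571203, 3025 bp wide with a score of 6.98, outside H3K79me2 peaks. The region on chromosome 1 from 44315836 to 44318303 carried H3K79me2 over 100% of its length in DMSO and after SGC0946 and over none of it after washout, together with its Pol II peak. A region on chromosome 18, from 74106701 to 74109290, was covered to 80.3% by H3K79me2 in DMSO, to 88.0% after SGC0946 and to 0% after washout. Among the 5 longest washout Pol II peaks absent from DMSO, 3 lay on the unplaced scaffold GL000226.1, and the other two on chromosome 1 from 228763822 to 228765675 and from 228774782 to 228776221. In total 9861 washout Pol II peaks, 18.9%, were absent from DMSO.

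H3K79me2 and Pol II peaks were then overlaid within each treatment. In DMSO 23067 H3K79me2 peaks, 27.1% (26.8 to 27.4%), shared a base with a Pol II peak, against a mean of 4.17% after circular shifts. After SGC0946 the number was 26933, or 28.9% (28.6 to 29.2%), against 4.47%. After washout it was 11153, or 16.5% (16.2 to 16.7%), against 2.32%. The observed share was 6.51, 6.47 and 7.09 times the shifted one. Of Pol II peaks, 36.5% lay on H3K79me2 in DMSO, 34.4% after SGC0946, and 13051 of 52178 after washout.

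DMSO H3K79me2 bases under Pol II peaks, 17.7 Mb, were covered to 90.7% by H3K79me2 peaks after SGC0946, and those outside Pol II peaks, 72.6 Mb, to 77.8%. After washout the values were 58.5% and 55.9%. Within the 10 groups by DMSO H3K79me2 score, coverage under Pol II minus coverage outside averaged 7.63 percentage points after SGC0946. This difference was positive in all 10 groups. After washout it was -7.47 points, between -11.6 and -4.74 and lower under Pol II in all 10 groups. The sign of the washout difference thus depended on matching for score. Matching was coarse in group 10, which ran from a score of 35.4 to 265 and held 10.9 of the 17.7 Mb under Pol II. Peak width was not matched. The bases of all H3K79me2 peaks that touched a Pol II peak were then pooled. After washout 58.5% of those under Pol II and 68.6% of the others were covered. After SGC0946 the values were 90.7% and 89.6%.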

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

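The count of joined regions reaching a score of 10 in the second weighing, the values by Pol II score in the third and the comparison with kept peaks of like width and score were chosen after related results were seen, as were the additional settings for the strongest peaks and for the bases under Pol II.

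Covered length moved in opposite directions for the 2 antibodies after SGC0946. It was lower than in DMSO for H3K79me2, by a difference of -6.96 Mb, and higher for Pol II, by 7.02 Mb. With 1 library on each side the difference between the antibodies was not tested.

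Of the 4249 DMSO H3K79me2 peaks in the top 5% by score, 39 were absent after washout; Pol II peaks covered a median of 70.3% of them in DMSO, against 24.6% of the 4210 kept and 19.3% of kept peaks of like width and score, while a top 5% Pol II peak lay on 46.2% of the 39, 48.3% of the kept and 36.3% of those of like width and score. Another cell line in the culture is argued against by 0 of the top 3398 washout peaks being absent from DMSO, and missing chromosome segments by the other DMSO peaks of both antibodies within 100 kb, of which washout kept a median of 51.4%. A less sensitive washout list stays open: an SGC0946 list shortened to the same share of DMSO peaks lacked 0 of the 4249, but the full list lacked 0 as well, so this comparison decides nothing, and the share absent went with score, 1.74% of the top 10%, 0.918% of the top 5% and 0.353% of the top 1%. Of the 39, 33 lay within 5 kb of a washout peak and 19 within 1 kb. Joined regions (peaks within 1 kb) with no washout peak held 6 of them. The joined regions around the 39 were covered by washout peaks to a median of 36.1%. When peaks were joined before ranking, 2 of 1255 regions in the top 5% by score were absent after washout. Local background in Pol II-dense chromatin may also account for the 39 absent peaks, as may the treatment itself, which was not tested.

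H3K79me2 peaks of 10 kb or more were fewer after SGC0946 (366) than in DMSO (676). Splitting by short gaps is consistent with the change of -6.37% that was left after peaks within 1 kb were joined. A less sensitive SGC0946 list stays open, since 1506 more joined regions than in DMSO reached a score of 10 while the peaks at that score covered less, 61.0 Mb against 67.0 Mb. Whether the short gaps come from the inhibitor, from sampling of reads or from the caller stays open too, since no value in the lists separates these and the effect of treatment was not tested.

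Within groups by score, DMSO H3K79me2 bases under Pol II peaks were covered less after washout than those outside. The mean difference was -7.47 percentage points. After SGC0946 they were covered more than those outside, and without score matching the washout difference was 2.54. A control library enriched in Pol II-dense chromatin could produce such a loss and cannot be told apart from a loss of the mark. Over the pooled bases of H3K79me2 peaks that touch a Pol II peak the difference was -10.2 points. Single peaks were not compared, so their width and score can enter this difference. Of the top 5% of Pol II peaks, 99.8% were kept. Washout coverage did not fall steadily with Pol II score, being 60.2%, 55.1% and 60.6% in groups 1, 9 and 10. Within groups by H3K79me2 score, however, Pol II group 10 minus group 1 was -6.87 points on average, between -18.2 and 1.62. That control stays open because control libraries were not analysed here. A lasting effect of SGC0946 on transcribed chromatin was not tested and stays open as well.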

How the results depend on the processing

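The settings for covered length, wide and strongest peaks, bases under Pol II and position within domains were chosen after seeing the data. No paired analysis was possible because each group is 1 library. The planned counts of genes, gene lists and their settings were not run, for want of an annotation of the build. In every setting run, washout lacked more DMSO peaks than SGC0946 did for both antibodies, and the share of H3K79me2 peaks on Pol II was lowest after washout. Restriction to chromosomes 1 to 22 and X left all 15 peak counts within 1.5 times. Counts outside that range follow, with SGC0946 against DMSO, washout against SGC0946 and washout against DMSO in this order. With both lists limited to a score of 10 or more, absent H3K79me2 peaks numbered 5396, 18200 and 15493, additional ones 4391, 968 and 742, absent Pol II peaks 3391, 10545 and 9216, and additional ones 5021, 704 and 913. H3K79me2 peaks on Pol II then numbered 8043 in DMSO, 8513 after SGC0946 and 3916 after washout. These were 26.8%, 23.2% and 21.4% of their lists, so the order of DMSO and SGC0946 turned round. With equal numbers of peaks, additional H3K79me2 peaks were 8950 after SGC0946 against DMSO and 13784 after washout against SGC0946, where 23404 were absent. For Pol II, 15595, 22017 and 21747 were absent and 17319, 14966 and 16283 additional, and 15853 SGC0946 H3K79me2 peaks lay on Pol II. Requiring 50% overlap gave 12604 additional washout Pol II peaks against SGC0946 and 14978 against DMSO. H3K79me2 peaks on Pol II were then 9949, 13120 and 4291 in DMSO, SGC0946 and washout. After joining peaks within 1 kb, absent H3K79me2 regions numbered 6311, 11713 and 10494, additional ones 6885, 4344 and 4249, absent Pol II regions 14454, 29485 and 25890, and additional ones 19531, 4593 and 5433. H3K79me2 regions on Pol II were 10806, 12066 and 7130. Limiting the score and joining shorten all lists by construction, equal numbers shorten the DMSO and SGC0946 lists and leave the washout lists whole, and 50% overlap is the stricter rule by construction. After joining, additional H3K79me2 regions outnumbered absent ones after SGC0946, the opposite of the order in the lists as deposited. The cause was not tested. H3K79me2 covered length after SGC0946 differed from DMSO by -11.1% to -4.11% and after washout by -48.9% to -34.1%, and for Pol II by 7.96% to 14.1% and -44.9% to -22.4%. The score-matched washout difference between bases under and outside Pol II was -4.36 percentage points at a score of 10 or more. It was -9.37 with equal numbers of peaks and -6.55 after joining. For SGC0946 these values were 7.51, 7.24 and 4.99. Without score matching, the washout difference between bases under and outside Pol II reversed to 2.54 percentage points, and the difference in absent Pol II peaks between lost and kept H3K79me2 reversed to 2.50. Unmatched comparisons mix peaks of different scores. Of the top 10% of DMSO H3K79me2 peaks, 148 were absent after washout, and of the top 1%, 3. After joining peaks within 1 kb, 2 of the 1255 regions in the top 5% by score were absent. Of the 5 regions named in each class, those with a score of 10 or more numbered 3 for H3K79me2 lost after SGC0946, 1 gained after SGC0946, 5 lost after washout and 0 gained after washout. For Pol II they numbered 0, 1, 2 and 3. With equal numbers of peaks all 5 of each class stayed in their list except Pol II lost after SGC0946, with 4. Unknown depth limits all counts of absent peaks.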

Other observations

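The comparison with kept peaks of like width, the additional settings and the regions named here were chosen after the data were examined.

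Most strong H3K79me2 peaks missing after washout sat within partly kept domains, but 6 of the 39 lay in joined regions with no washout peak at all. These were on chromosome 22 from 39711540 to 39715650, on chromosome 9 from 130210821 to 130213723 and from 19377106 to 19380270, on chromosome 1 from 26799042 to 26801928, on chromosome 19 from 49999657 to 50001455, and the chromosome 8 region described in the report. The chromosome 22 region had the highest DMSO score of these 6, 143, and its nearest washout peak was 29763 bp away. Pol II peaks covered it to 98.5% in DMSO and 98.0% after washout. The chromosome 9 region at 130210821 and the one on chromosome 19 were covered by Pol II to 100% in both, while the one at 19377106 went from 82.4% to 65.6%. Of the 39, 12 were covered by washout Pol II peaks to 90% or more, or 30.8%, against 4.44% of the 4210 strong peaks that kept H3K79me2 and 3.46% of kept peaks of like width and score. Pol II coverage already differed in DMSO, with medians of 70.3%, 24.6% and 19.3%, and was not matched. Any washout Pol II peak lay on 79.5% of the 39, 79.2% of the kept and 69.0% of kept peaks of like width and score.

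Unplaced scaffolds did not share the lower Pol II coverage after washout. Pol II peaks covered 76000 bp of them in DMSO, 74458 bp after SGC0946 and 87091 bp after washout. H3K79me2 peaks covered 47845 bp, 39504 bp and 23032 bp. The Pol II values rest on 84, 90 and 89 peaks. Washout Pol II peaks of 2723, 1973 and 1565 bp that were absent from DMSO lay on 1 scaffold, GL000226.1.

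One hypothesis was that H3K79me2 loss grows with distance from the Pol II end of a domain. From end to end of 1612 domains, the difference of 33.6 points after washout goes with it. The fall was not steady, since coverage was 86.0% in part 1, 90.3% in part 2 and 52.4% in part 5. The end-to-end difference was 28.0 in the 477 domains of 10 kb or more, 52.6 at a score of 10 or more and 47.0 after joining peaks within 1 kb. The score limit also removes weaker washout peaks, so the larger difference there does not separate the hypothesis from a less sensitive washout list. The first and last parts are also the edges of DMSO peaks, where a narrower call trims coverage. The 3 inner parts, at 90.3%, 82.8% and 69.3%, lie further in, but a call shortened by more than 1 part reaches them as well. Trimming at the edges is therefore not excluded. Over the pooled bases of H3K79me2 peaks of any width that touch a Pol II peak, the difference under minus outside Pol II was -10.2 points. That set includes narrower peaks and does not measure position along a domain, so the value does not decide the hypothesis. Growth of the loss with distance remains a hypothesis. A lower signal at the far end in DMSO, together with a less sensitive washout list, could give the same shape. The lists hold 1 score per peak, so this was not tested.

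A second hypothesis was that Pol II is lost together with H3K79me2. Of 7476 DMSO Pol II peaks on H3K79me2 peaks that were absent after washout, 57.9% were absent from the Pol II washout list. Of 27405 on H3K79me2 peaks that were kept, 61.6% were absent after matching on Pol II score. The difference of -3.73 percentage points, and of -1.06 at a score of 10 or more, gives no sign of joint loss where whole H3K79me2 peaks were absent. Without the score matching it was 2.50 points, which is still small. An H3K79me2 peak counted as kept when 1 bp of it was left, so loss limited to the bases under a Pol II peak was missed. Joint loss within kept H3K79me2 peaks can therefore be neither shown nor excluded by these values.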
